A study of Mus musculus with 3 samples.

How the data were processed

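The measured material was the stromal vascular fraction of mouse epididymal white adipose tissue, the non-adipocyte cells released by digesting the fat pad. Single-cell RNA was read in 3 libraries from C57BL/6 males, with 10 mice pooled at postnatal day 3 (P3), 5 mice at postnatal day 7 (P7) and 5 mice at 5 weeks of age. Per the labels' protocols these are 3' version 3 libraries of the 10x Chromium system, read over 26 cycles of read 1, 58 cycles of read 2 and 8 index cycles. The protocols also describe an isolation of mesothelial cells, the flat epithelium-like layer that covers the fat pad, and do not state whether such cells were added to the P7 library.

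The deposited matrices hold counts, that is raw numbers of unique molecular identifiers (UMIs) per gene and barcode, with no normalisation by the authors. Per the submitters' processing notes, reads were aligned to mm10 with Cell Ranger 3.1.0 and examined with Seurat 4.0.3. Per the file headers the matrices of P3 and P7 were written by software version 3.1.0 and list 31053 genes, and the 5-week matrix was written by version 3.0.0 and lists 27998 genes. The software and gene list therefore differ between the 5-week library and the others in the same way as adult and perinatal age. Each matrix is unfiltered and lists all 6794880 barcodes. Only the 27514 Ensembl IDs present in every gene list were used for the comparisons. The 3539 IDs listed for P3 and P7 alone and the 484 listed for 5 weeks alone were left out of them. Shared IDs carried a differing symbol in 1027 cases and were matched by ID. Gene positions come from GENCODE vM21 on GRCm38 (mm10), which had coordinates for 99.8% of the IDs specific to P3 and P7 and for 50% of those specific to 5 weeks.

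Cells were called, clustered and compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scanpy 1.11.5 with its Scrublet, igraph 0.11.9 and scikit-learn 1.9.0, and drawn with matplotlib 3.10.9. A barcode was kept as a cell with at least 1000 UMIs, at least 500 genes, at most 10% mitochondrial UMIs and no Scrublet doublet call at an expected rate of 0.06. Scrublet removed 2.54% of the passing barcodes at P3, 6.13% at P7 and 7.64% at 5 weeks. Barcodes of at most 100 UMIs were summed per library as a measure of free RNA, and they held 1.74% of UMIs at P3, 2.11% at P7 and 4.95% at 5 weeks.

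Each library was clustered on its own after scaling to 10000 counts per cell and log1p, with 2000 variable genes, cell cycle genes left out of them, 30 principal components, 15 neighbours and Leiden resolution 1.0. Clusters were named from fixed marker lists. A name needed a mean marker score of at least 1.5 (log2 over the median cluster, pseudocount 5 CPM) and at least 3 markers above 2-fold. No unrelated second class was allowed to reach a score of 2.0 together with a share of 0.45 of the first score. Among the 10 leading genes of at least 100 CPM, markers of another class were not allowed to outnumber the cluster's own. A cluster with a median under 1/3 of the library's median UMIs also needed a marker of its own among them. Macrophages, monocytes and dendritic cells were named as 1 myeloid class because they share leading genes, and clusters with a higher macrophage than dendritic score were then taken as macrophage- or monocyte-like. Progenitor-like cells were clustered again with 20 components at resolution 0.5, and a sub-cluster was named for the subgroup with the highest score if that reached 0.5 with at least 5 markers above 1.5-fold, unless markers of another class or subgroup outnumbered its own among its 10 leading genes. The limits of second class share and score, the sub-cluster rule, the joined myeloid class and the rule for genes set apart by their ratios were set after the data had been seen. Cells in unnamed clusters were 7.70% at P3, 3.38% at P7 and 17.8% at 5 weeks, and they were left out of the class comparisons.

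UMIs were summed per class and library and scaled to the class sum as CPM. With 1 library per age no test was made, and no p-value or standard error was computed from cells. Shares carry exact Clopper-Pearson 95% intervals, levels exact Poisson intervals, and ratios exact conditional binomial 95% intervals for 2 Poisson counts. All intervals, and limits for counts of 0 based on a floor of 3 counts, cover counting error only. Genes were counted as higher or lower beyond 2-fold if the higher library had at least 50 CPM and the interval lay beyond 1. Classes with fewer than 50 cells in either library were not compared. For 31 fixed gene lists the median log2 ratio over members with at least 10 CPM in either library was set against 10000 random lists of the same size matched on mean expression, as a description without a p-value, where at least 5 members were measured. Members of a list were counted as higher or lower, also where called beyond 2-fold, by a ratio of at least 2-fold alone. These counts of members used neither the minimum of 50 CPM nor the interval, and a count of 0 stood at the floor. Genes used to name subgroups were left out of the comparisons between and within subgroups.

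Genes were chosen for naming by a rule set in advance. It takes the 8 largest ratios per direction among genes with at least 50 CPM and 30 UMIs in the higher library, without mitochondrial, ribosomal, haemoglobin, predicted or antigen receptor genes, and up to 4 members of each fixed list by absolute ratio. Pdgfra, Pdgfrb, Ly6c1, Cd9, Dpp4, Pparg, Fabp4, Cebpa, Col1a1, Igf2, Wt1 and Mki67 were always named. In other classes the rule takes the 4 largest ratios per direction and the class markers, and between subgroups up to 4 members per list. The same selection of list members was extended to the other classes after the data had been seen. The marker lists, gene lists, filters, main settings, naming rule and most alternatives were chosen before the data were examined. Genes set apart by their ratios were those at least 8-fold apart in one direction in progenitor-, mesothelial- and myeloid-like cells and in low-count barcodes. Their levels also had to lie within 4-fold across the classes in the higher libraries. The rule used no annotation, and the ratios were not required to be alike.

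Alternatives covered a looser minimum of 500 UMIs and 200 genes, a minimum relative to the 99th percentile of the top 5000 barcodes, Scrublet calls kept in, Leiden resolutions 0.5 and 2.0, joint clustering, cells called by markers, scaling by trimmed mean of ratios (TMM, trims of 30% and 5%), means over cells, thinning to 2000 UMIs, a marker gate for progenitors, cells without cycling UMIs, minimums of 10 and 200 CPM, no minimum for lists, other cycling calls, and other sub-cluster settings. Chosen after seeing the data were a mitochondrial limit of 20%, inclusion of a P3 cluster with a pericyte marker among its leading genes, omission of genes overlapped by unshared gene models or set apart by their ratios, and the use of scaling, depth and minimum alternatives in other classes and subgroups. The ratio procedure was tested on simulated data, with class sums drawn from the 5-week progenitor profile. For each pair of ages it called 100 of 100 genes made 3-fold different, 0 of 100 made 1.5-fold different, and 0 of at least 2694 left alike. The draws held counting error only, and the changed genes stood well above the minimum of 50 CPM. The outcome therefore followed from the 2-fold limit and does not measure variation between libraries or animals.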

Results

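Single-cell RNA was measured in the stromal vascular fraction of epididymal white fat from C57BL/6 male mice at postnatal day 3 (P3), at postnatal day 7 (P7) and at 5 weeks of age. Each age has 1 library, made from 10 pooled mice at P3 and from 5 pooled mice at P7 and at 5 weeks. The P3 library held 81307312 unique molecular identifiers (UMIs), the P7 library 76968353 and the 5-week library 82940960. After filtering, 5689 cells were kept at P3 with a median of 8797 UMIs per cell, 10905 at P7 with a median of 4216, and 7510 at 5 weeks with a median of 5171. There are no replicate libraries, so each comparison compares those libraries, not the conditions, and intervals are exact 95% intervals of counting error only. The comparisons address the question in the study's title, how perinatal fat progenitors differ from adult ones.

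Mesothelial-like cells held a larger share of the perinatal libraries, and blood vessel cells a larger share of the 5-week library. Progenitor-like cells, the Pdgfra-bearing fibroblast type from which fat cells arise, formed a large class at every age. Lymphatic endothelial, neutrophil, B cell, mast cell and adipocyte-like clusters were named in both perinatal libraries and in none at 5 weeks. At 5 weeks a cluster of 52 cells scored highest as adipocyte, and another of 59 cells was led by the B cell genes Jchain and Cd79a. Both also scored as endothelial and stayed unnamed, so these classes are not shown to be absent. Clusters named as epididymal or other epithelium, with Epcam and Spink8 among their leading genes, held 36 cells at P3 and 70 at P7. None were named at 5 weeks, and whether the dissection of the fat pad differed between the libraries was not tested. Progenitor-like cells made up 34.3% of cells at P3 [33.0 to 35.5], 49.1% at P7 [48.1 to 50] and 39.3% at 5 weeks [38.2 to 40.4]. A further 7.01% of P3 cells scored highest as progenitor and stayed unnamed for a pericyte marker among their leading genes. With them, 2349 of 5689 P3 cells were progenitor-like against 2949 of 7510 at 5 weeks, so the order of P3 and 5 weeks turned. The order also turned with a mitochondrial limit of 20%, at 39.9% and 33.4%. Mesothelial-like cells made up 33.3% at P3, 18.4% at P7 [17.6 to 19.1] and 6.35% at 5 weeks [5.81 to 6.93]. The protocols mention a separate isolation of mesothelial cells at P7 and do not state whether such cells entered this library. Myeloid-like cells, which are macrophages, monocytes and dendritic cells, held 12.7% at P3 [11.8 to 13.6], 15.8% at P7 [15.2 to 16.5] and 21.7% at 5 weeks [20.8 to 22.7]. With Scrublet calls kept in, the order of P7 and 5 weeks turned, at 17.5% and 15.6%. Endothelial-like cells held 0.492% at P3 [0.327 to 0.711], 1.14% at P7 [0.947 to 1.35] and 13.2% at 5 weeks [12.4 to 14.0]. A further 14.4% of 5-week cells scored as endothelial together with another class and stayed unnamed. T, NK and innate lymphoid cells were 1.18% at P3, 5.70% at P7 and 1.61% at 5 weeks. A 5-week cluster of 103 cells led by Il5, Gata3 and Csf2 stayed unnamed as shallow, although clusters with like leading genes were counted at P3 and P7. Lymphatic endothelial-like cells were 2.22% at P3, 0.339% at P7 and 0 of 7510 cells at 5 weeks. Adipocyte-like cells were 1.90% at P3 and 2.23% at P7, and neutrophils 1.88% and 1.36%.

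**Figure D1:**
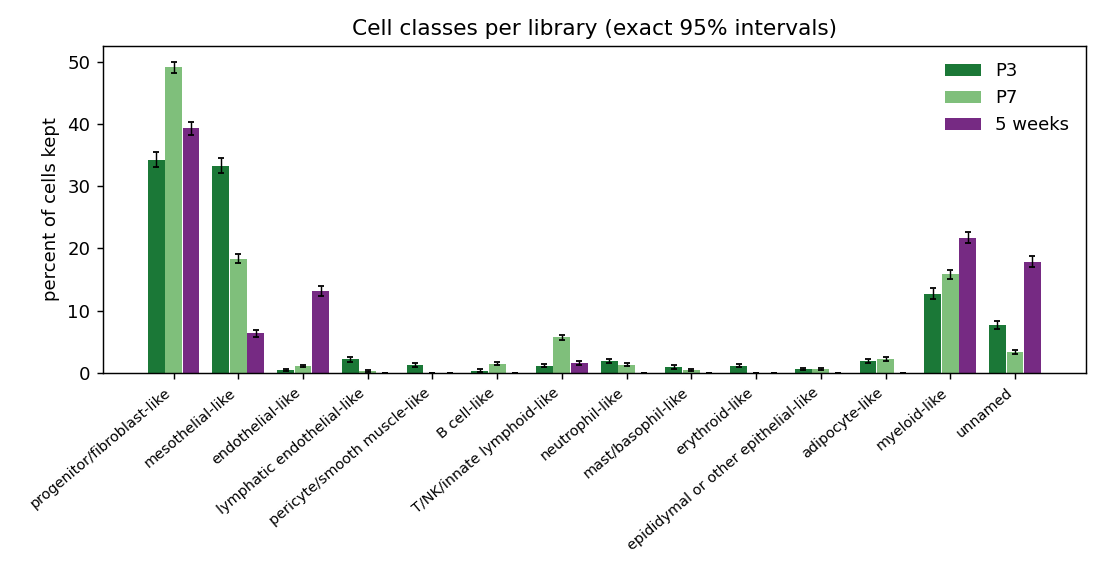
Percent of kept cells in each named class (y axis) for the P3, P7 and 5-week libraries (bars), with exact 95% binomial intervals. Mesothelial-like cells stand at 33.3%, 18.4% and 6.35%, and endothelial-like cells at 0.492%, 1.14% and 13.2%.

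Against the 5-week library, P3 progenitor-like cells carried much higher RNA of fetal growth genes, of embryonic mesenchyme and of the cell cycle. They carried much lower RNA of chemokines, of antigen presentation, of interferon response, of basement membrane and of metal-binding and glucocorticoid-responsive genes. Dlk1 is an imprinted gene that restrains fat cell formation, H19 and Cdkn1c are imprinted growth regulators, and Ptn and Mdk are related secreted growth factors. Agtr2, the angiotensin receptor typical of fetal mesenchyme, was also higher at P3. Dlk1 (ENSMUSG00000040856, chromosome 12, 109452823 to 109463336 on mm10, GENCODE vM21) stood at 3217 CPM at P3 and 9.03 at 5 weeks, a log2 ratio of 8.48 [8.24 to 8.72]. H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143) stood at 1307 and 65.2 CPM, a log2 ratio of 4.32 [4.24 to 4.41]. Ptn (ENSMUSG00000029838, chromosome 6, 36714929 to 36810220) stood at 3299 and 91.6 CPM, with a log2 ratio of 5.17. Cdkn1c (ENSMUSG00000037664, chromosome 7, 143458339 to 143461050) stood at 1889 and 99.2 CPM, with a log2 ratio of 4.25. Mdk had a log2 ratio of 4.85 [4.71 to 4.99] and Agtr2 of 7.38 [6.91 to 7.89]. Igf2, whose gene is overlapped by a model in only some of the gene lists, was low at both ages, at 20.3 CPM at P3 and 3.07 at 5 weeks. Over 20 imprinted growth genes the median log2 ratio was 2.0, with 14 higher beyond 2-fold and 0 lower, at percentile 100 of random matched lists. Over 24 genes of perinatal or embryonic mesenchyme the median was 2.23, with 17 higher and 2 lower, also at percentile 100.

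Matrix genes of the P3 progenitors differed in both directions. The elastic fibre genes Mfap4 and Fbn2 were higher, the fibrillar collagen gene Col1a1 was modestly higher, and the basement membrane collagen gene Col4a1 was lower. Mfap4 stood at 754 CPM at P3 and 61.5 at 5 weeks, a log2 ratio of 3.61, and Fbn2 had a log2 ratio of 3.43. Col1a1 stood at 10720.0 and 4858 CPM, a log2 ratio of 1.14. Thbs1, which activates latent TGF-beta, went the other way, with 62.8 CPM at P3 and 1679 at 5 weeks. Over 37 fibrillar and interstitial matrix genes the median log2 ratio was -0.13, with 9 higher and 6 lower. Col4a1 (ENSMUSG00000031502, chromosome 8, 11198423 to 11312826) stood at 242.5 and 2341 CPM, a log2 ratio of -3.27 [-3.32 to -3.23]. Over 14 basement membrane genes the median was -1.77, with 11 lower and Npnt as the 1 higher member, at percentile 0.01. Acta2, a contractile actin, was higher with a log2 ratio of 6.39, although its 124 CPM in P3 progenitors lay below the 244 CPM of P3 free RNA and the class holds a sub-cluster of 100 cells with the pericyte gene Rgs5 and Acta2 among its leading genes. Over 25 TGF-beta and contractile genes the median was -0.33, with 8 higher and 10 lower. Position genes were higher at P3, with a median of 1.44 over 16 Hox genes and log2 ratios of 4.45 for Hoxa9 and 4.28 for Hoxa10.

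Many immune genes were lower at P3 than at 5 weeks. Ccl2 and Ccl7 recruit monocytes, Ccl11 recruits eosinophils, Il6 is an inflammatory cytokine and C3 is the central complement protein. Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453) stood at 153 CPM at P3 and 6491 at 5 weeks, a log2 ratio of -5.40 [-5.46 to -5.35]. Ccl7 stood at 109 and 5328 CPM, Ccl11 at 37.5 and 1711, and Il6 at 15.9 and 797. C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136) stood at 127 and 2522 CPM, a log2 ratio of -4.31. H2-D1 (ENSMUSG00000073411, chromosome 17, 35262730 to 35267499), a classical MHC class I gene, stood at 44.4 and 641 CPM, a log2 ratio of -3.85. Its 5-week level lay below the 1030 CPM of 5-week free RNA. Over 28 chemokines and inflammatory mediators the median log2 ratio was -2.78, with 22 lower, 2 higher and percentile 0.0. Over 15 MHC class I genes it was -2.27, with 12 lower and 0 higher. Over 26 interferon response genes it was -1.51, with 16 lower and 1 higher, including log2 ratios of -4.98 for Gbp2 and -4.91 for Ifit1. Over 11 complement genes it was -1.07, with 6 lower and 2 higher. The metallothionein Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) stood at 9.0 and 1344 CPM, a log2 ratio of -7.22, and Mt1 at 111 and 5639. Over 17 glucocorticoid-responsive genes the median was -1.32, with 11 lower and 1 higher.

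Surface and fat cell genes were lower at P3 in part. Pdgfra (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215) stood at 116 CPM at P3 and 433 at 5 weeks, a log2 ratio of -1.90 [-1.97 to -1.83], while Pdgfrb had a log2 ratio of -0.14. Dpp4, a marker of interstitial progenitors, stood at 8.16 and 72.3 CPM, Ly6c1 had a log2 ratio of -2.10 and Cd9 of -1.74. Over 13 surface marker genes the median was -1.74, with 9 lower and 0 higher. Pparg, the master regulator of fat cell formation, differed little, at 22.2 and 18.5 CPM, and Cebpa had a log2 ratio of -0.21. Fabp4 was lower with a log2 ratio of -2.11, but its levels lay below the free RNA of each library. Over 25 adipogenic and lipid storage genes the median was -0.63, with 8 lower and 2 higher. Wt1 had a log2 ratio of -0.79. Medians were 0.70 for 19 glycolysis and hypoxia genes, -0.64 for 20 cholesterol synthesis genes, -0.74 for 27 growth factor axis genes and -0.12 for 31 early response genes. Wnt pathway genes had a median of 0.05 over 16 members, which turned to -0.38 with TMM scaling.

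**Figure D2:**
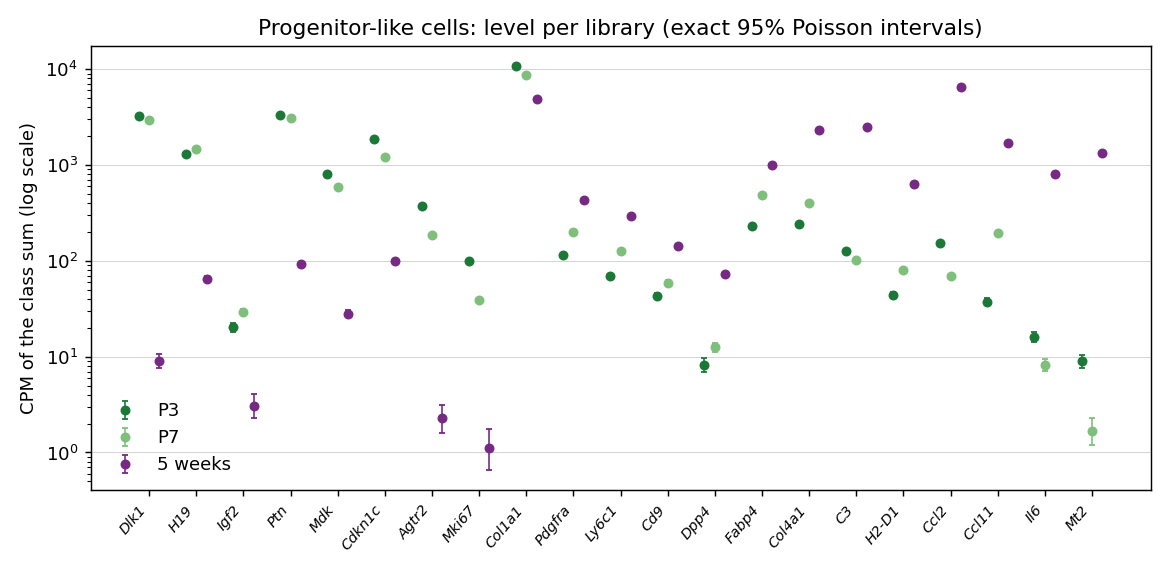
Level in progenitor-like cells (y axis, CPM of the class sum, log scale) of 21 genes in the P3, P7 and 5-week libraries (points), with exact 95% Poisson intervals. Dlk1 stood at 3217, 2930.0 and 9.03 CPM, and Ccl2 at 153, 69.2 and 6491.

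In P3 over 5 weeks, 857 genes were higher and 780 lower beyond 2-fold, and with TMM scaling the split was 364 higher and 1035 lower. The median log2 ratio was 0.224 over the 3755 genes at the minimum of 50 CPM, and -0.308 over the 3382 genes at the minimum with TMM scaling. Among named genes not set apart by their ratios, Igfbp2 had the largest ratio, at 9.62 [7.76 to 12.66] with 2 UMIs at 5 weeks, and its 96.4 CPM in P3 progenitors lay below the 177 CPM of P3 free RNA. Lsm7 and Fau, with log2 ratios of 11.37 and 8.66, were at least 8-fold higher also in mesothelial- and myeloid-like cells and in free RNA. Genes at least 8-fold apart in one direction, higher or lower, in all of these and with levels within 4-fold across the classes were set apart and counted separately. Without such genes 850 were higher and 775 lower.

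P7 progenitor-like cells were compared with the same 5-week library. Fetal growth and embryonic mesenchyme genes were again higher, and chemokine, class I, interferon and glucocorticoid-responsive genes again lower. The cholesterol synthesis and early response genes, which were nearer the 5-week level at P3, were lower at P7. Dlk1 stood at 2930.0 CPM at P7, a log2 ratio of 8.34 [8.11 to 8.59] over 5 weeks, and H19 at 1485 CPM, with a log2 ratio of 4.51. Log2 ratios were 5.08 for Ptn, 4.4 for Mdk, 3.62 for Cdkn1c and 6.34 for Agtr2. Over 18 imprinted growth genes the median was 2.30, with 13 higher and 0 lower. Over 23 perinatal or embryonic mesenchyme genes it was 2.21, with 13 higher and 2 lower, and over 14 Hox genes it was 1.23 with 10 higher. Mfap4 had a log2 ratio of 3.61, and Mfap2 stood at 1602 CPM at P7 and 253.5 at 5 weeks. Ccl2 stood at 69.2 CPM at P7, a log2 ratio of -6.55 [-6.62 to -6.48], and Il6 at 8.24 CPM. Over 28 chemokines and inflammatory mediators the median was -3.08, with 24 lower and 2 higher. Medians were -1.86 for 15 MHC class I genes, -1.83 for 26 interferon response genes and -1.30 for 14 basement membrane genes. Mt1 stood at 27.8 CPM and Mt2 at 1.67, and over 16 glucocorticoid-responsive genes the median was -2.06, with 12 lower and 0 higher. Over 20 cholesterol synthesis genes the median was -1.40, with 12 lower, including log2 ratios of -3.12 for Insig1 and -3.10 for Idi1. Over 31 early response genes the median was -1.27, with 17 lower and 3 higher, including log2 ratios of -5.22 for Egr2 and -3.71 for Nr4a1. Pdgfra had a log2 ratio of -1.13, Ly6c1 of -1.22 and Dpp4 of -2.53. Pparg was higher with a log2 ratio of 0.89, and over 26 adipogenic genes the median of 0.06 turned to -0.31 with TMM scaling. Beyond 2-fold 695 genes were higher and 656 lower, and with TMM scaling 256 were higher and 890 lower.

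Between the perinatal ages the progenitors were much closer. P3 cells carried higher RNA of cell cycle genes and of some cholesterol synthesis and chemokine genes, and lower RNA of the lipid genes Lpl and Cd36 and of chemokine Ccl11. Beyond 2-fold 90 genes were higher at P3 and 44 lower. Igfbp2, a binding protein for insulin-like growth factors, stood at 96.4 CPM at P3 and 10.4 at P7, a log2 ratio of 3.21 [3.02 to 3.41] that carries the limit of free RNA given above. Ier3, an early response gene, stood at 382 and 76.3 CPM, a log2 ratio of 2.33, and the glycolytic gene Gapdh had a log2 ratio of 1.74. Early response genes as a list had medians over 5 weeks of -0.12 at P3 and -1.27 at P7. Dissociation as a source of differences between P3 and P7 was not tested. Nfkbia, the inhibitor of NF-kappaB and a target of it, stood at 516 and 217.5 CPM, and Ccl2 had a log2 ratio of 1.15 at levels below the 454 and 597.5 CPM of P3 and P7 free RNA. Over 18 chemokines and inflammatory mediators the median was 0.78, with 6 higher and 1 lower. The lower member was Ccl11, at 37.5 CPM at P3 and 194.5 at P7, a log2 ratio of -2.37 [-2.49 to -2.26]. Over 18 cholesterol synthesis genes the median was 0.61, with 4 higher and 0 lower, and Hmgcs1 had a log2 ratio of 1.56. Igfbp3 stood at 31.9 CPM at P3 and 158 at P7, Wnt5a had a log2 ratio of -1.75 and Apoe of -1.57. Lpl stood at 1027 and 2076 CPM, Cd36 had a log2 ratio of -1.62 and Pdgfra of -0.77. Medians were -0.56 for 12 MHC class I genes, -0.59 for 14 basement membrane genes and -0.42 for 25 adipogenic genes, of which 3 were lower and 0 higher beyond 2-fold. Imprinted genes had a median of -0.02 and embryonic mesenchyme genes of 0.07.

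**Figure D3:**
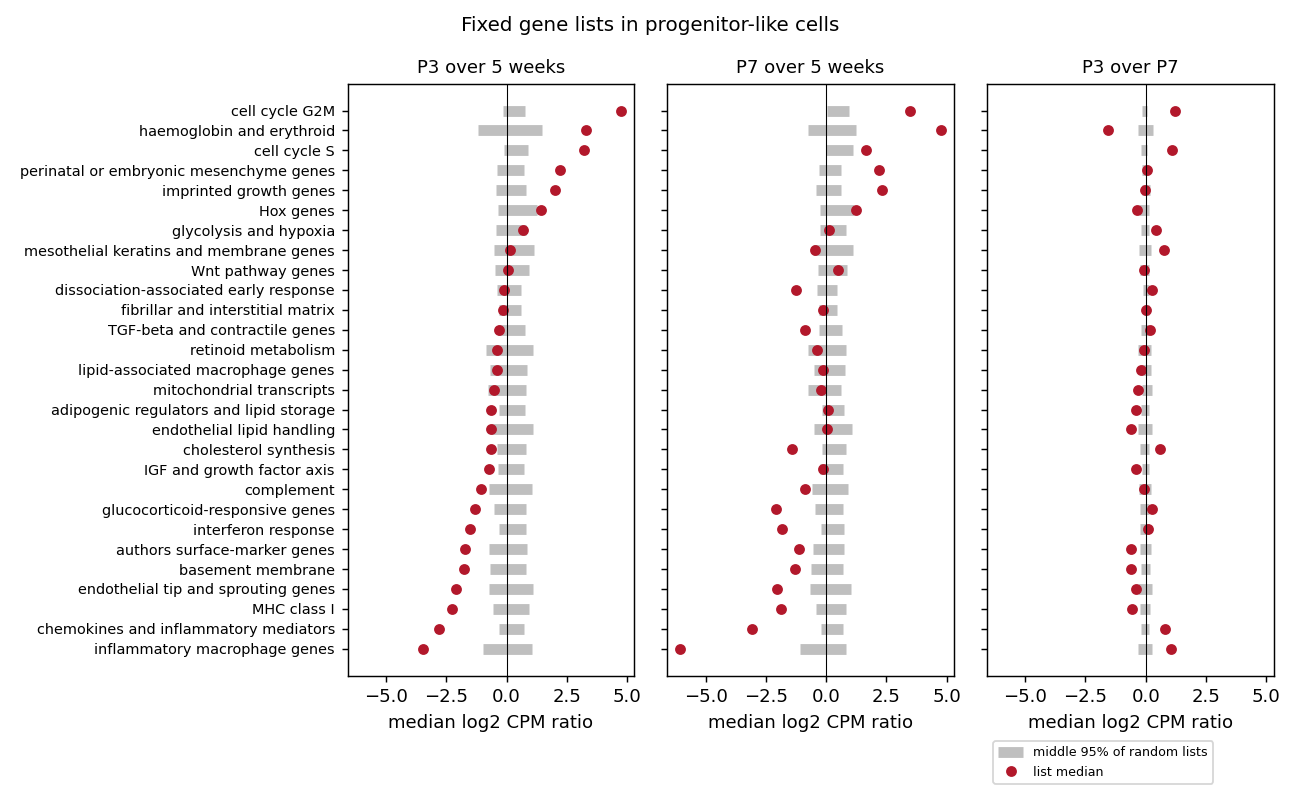
Median log2 CPM ratio (x axis) of each fixed gene list (y axis) in progenitor-like cells for the pairs P3 over 5 weeks, P7 over 5 weeks and P3 over P7, with the middle 95% of random matched lists in grey. Chemokines and inflammatory mediators stood at -2.78, -3.08 and 0.78, and with TMM scaling the Wnt list turned to -0.38 and the keratin list to -1.39 in P3 over 5 weeks, and the adipogenic list to -0.31, the glycolysis list to -0.33 and the endothelial lipid list to -0.31 in P7 over 5 weeks.

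Lists made for other cell types were read in progenitor-like cells as well. Inflammatory macrophage genes, which share Ccl2, Ccl7 and Il6 with the chemokine list, had medians of -3.46 in P3 over 5 weeks, -6.05 in P7 over 5 weeks and 1.04 in P3 over P7. Endothelial tip genes, which share type IV collagens with the basement membrane list, had medians of -2.11, -2.04 and -0.42. Haemoglobin and erythroid genes had medians of 3.31, 4.76 and -1.56, with Hbb-bs at 454 CPM in P3 progenitors and 5987 in P3 free RNA. Retinoid metabolism genes had medians of -0.38, -0.38 and -0.07, and mitochondrial transcripts of -0.53, -0.21 and -0.32. Keratin and membrane genes of mesothelium had medians of 0.16, -0.48 and 0.74, with Krt19 at 33.0 CPM in P3 progenitors and 456 in P3 free RNA. Lipid-associated macrophage genes had medians of -0.39, -0.15 and -0.21, and endothelial lipid handling genes of -0.63, 0.04 and -0.63. Sex-linked genes were read as a check for males, and fewer than 5 measured members leave them without a percentile.

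Transcripts of cycling cells were found in more progenitors at P3 than at P7, and in few at 5 weeks. Mki67 and Top2a mark cells in the active cell cycle, and Ube2c, Rrm2 and Stmn1 serve mitosis, nucleotide supply and spindle growth. After each cell was thinned to 2000 UMIs, 15.6% of P3 progenitor-like cells carried Mki67 or Top2a (294 of 1885, 14.0 to 17.3). The share was 5.61% at P7 (271 of 4835, 4.97 to 6.29) and 0.458% at 5 weeks (13 of 2840, 0.244 to 0.782). Before thinning the progenitors had medians of 8662.5, 4041 and 5424 UMIs, and the shares were 28.1%, 8.13% and 1.49%. Neutrophil-like cells gave 2 of 49 cells or 4.08% at P3 [0.498 to 14.0] at a median of 1852 UMIs before thinning. At P7 they gave 0 of 45, which by the floor of 3 counts, not the exact interval, allows up to 6.67%. Their median was 1350 UMIs, and none were named at 5 weeks. These few cells bound a background share only loosely, and Camp and Ngp, genes of immature neutrophils, were among the leading genes of their clusters. Mki67 and Top2a together stood at 240.8 CPM in P3 progenitors against 181 in P3 free RNA, at 88.4 against 106 at P7, and at 2.89 against 37.8 at 5 weeks. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361) had log2 ratios of 6.51 [5.84 to 7.26] in P3 over 5 weeks, 5.13 in P7 over 5 weeks and 1.38 [1.27 to 1.5] in P3 over P7. In P3 over 5 weeks the median was 4.76 over 47 G2M genes, with 43 higher, and 3.22 over 37 S phase genes, with 34 higher. In P7 over 5 weeks it was 3.46 over 38 G2M genes and 1.65 over 26 S phase genes. In P3 over P7 it was 1.23 for G2M genes, which turned to -0.05 in cells without cycling UMIs, and 1.08 for S phase genes. The share of mesothelial-like cells was 13.3% at P3, 12.4% at P7 and 3.49% at 5 weeks. Macrophage- or monocyte-like cells gave 21.1%, 13.1% and 5.57%. Lymphoid cells gave 34.1%, 18.5% and 30.3%, but these sets are unlike. Before thinning they held 22 B cells at P3 and 164 at P7, while no B cells were named at 5 weeks. The 5-week set also lacks the unnamed cluster led by Il5 and Gata3.

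**Figure D4:**
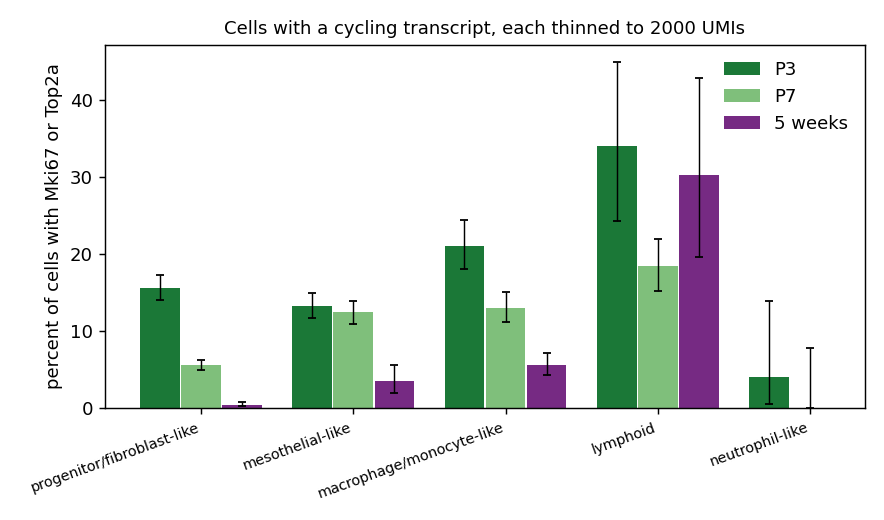
Percent of cells with Mki67 or Top2a after thinning each to 2000 UMIs (y axis), per class, for the P3, P7 and 5-week libraries (bars), with exact 95% binomial intervals. Progenitor-like cells stand at 15.6%, 5.61% and 0.458%, and neutrophil-like cells at 4.08% at P3 and 0 at P7.

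Some progenitor sub-clusters of each library were named for a fibro-inflammatory type marked by Dpp4, Pi16 and Ly6c1 (FIP-like). Others were named for a committed preadipocyte type marked by Pparg, Fabp4 and Lpl (APC-like) or for a type marked by F3. The sub-clusters were formed from the expression of these same cells, and only the genes used for naming were left out afterwards. Differences and gene counts between subgroups of a library are therefore not independent of the clustering. Ly6a was among the leading genes of the FIP-like sub-clusters at P3 and P7, and Mfap5 at P7. At every age FIP-like cells had higher RNA of Mfap5 of elastic fibres, of the stem cell antigens Ly6a and Thy1, and of the ligand Tgfb2. APC-like cells carried more of the fat cell regulator Cebpa at P7 and 5 weeks, and more of the basement membrane gene Nid2 at every age. FIP-like cells numbered 252 at P3, 1557 at P7 and 921 at 5 weeks, APC-like cells 137, 1831 and 1108, and F3-like cells 0, 683 and 210. The progenitor-like cells numbered 1950, 5352 and 2949. At P3 most of them stayed without a subgroup name, so the P3 subgroup values rest on a minority of the class. At resolution 1.0 the P7 groups were 771 FIP-like, 296 and 471 APC-like and 440 F3-like cells, and no F3-like cells were named at 5 weeks, so the F3-like comparison with 5 weeks rests on the coarser sub-clusters. A P3 sub-cluster of 100 cells scored as F3-like and stayed unnamed for pericyte genes among its leading genes. Mfap5 stood at 3873 CPM in FIP-like and 363 in APC-like cells at P3, at 4457 and 965 at P7, and at 3596 and 492 at 5 weeks. Ly6a had log2 ratios of FIP-like over APC-like cells of 4.98, 3.16 and 1.55 at P3, P7 and 5 weeks, Thy1 of 3.69, 2.65 and 2.03, and Tgfb2 of 1.83, 1.80 and 2.43. Nid2 had log2 ratios of -1.68, -1.25 and -1.33, and Cebpa of -2.08 at P7 and -1.33 at 5 weeks. Over TGF-beta and contractile genes the median was 1.09 at P3, 0.43 at P7 and 0.67 at 5 weeks. Over matrix genes it was 0.43, 0.42 and 0.17, over surface markers 0.87, 0.55 and 0.14, and over adipogenic genes -0.63, -0.00 and -0.08. Chemokines and inflammatory mediators were higher in FIP-like cells at P3, with a median of 0.85, 10 higher and 3 lower among 21. Ccl2, Tnfaip6 and Ccl7 were among the leading genes of that sub-cluster, and chemokines were not kept out of the clustering. The value is therefore not independent of how the sub-clusters were formed. At P7 the median was -0.22, which turned to 0.07 with finer sub-clusters, and at 5 weeks it was -0.60, with 6 higher and 11 lower among 28. Ccl7 stood at 343 CPM in FIP-like and 25 in APC-like cells at P3, and at 3800 and 6841 at 5 weeks. Il6 stood at 372 and 1111 CPM at 5 weeks. Imprinted genes had medians of -0.11, which turned to 0.06 with TMM scaling, 0.10 and 0.69. Beyond 2-fold, FIP-like over APC-like, 303 genes were higher and 194 lower at P3, 121 and 70 at P7, and 291 and 283 at 5 weeks. With TMM scaling the P3 split was 410 and 132, and the P7 split 145 and 61. Resolution 1.0 gave 253 and 169 at P7, thinning gave 301 lower at P3, and joint clustering gave 189 higher at 5 weeks.

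**Figure D5:**
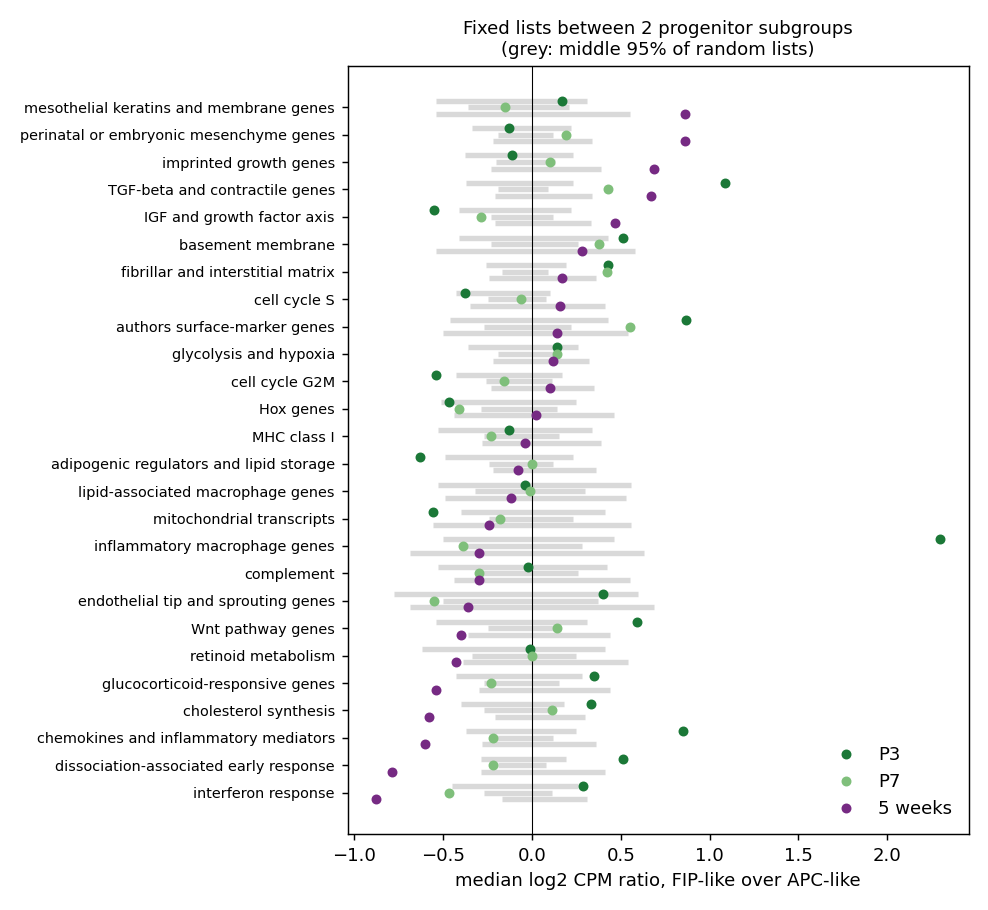
Median log2 CPM ratio of FIP-like over APC-like cells (x axis) for each fixed gene list (y axis) at P3, P7 and 5 weeks (points), with the middle 95% of random matched lists in grey. Chemokines stand at 0.85, -0.22 and -0.60 and TGF-beta genes at 1.09, 0.43 and 0.67, and with TMM scaling the P3 medians of imprinted, embryonic mesenchyme, MHC class I, complement, retinoid and lipid-associated genes turned to 0.06, 0.04, 0.04, 0.15, 0.16 and 0.13, the P7 medians of lipid-associated and S phase genes to 0.06 and 0.01, and the 5-week median of S phase genes to -0.09.

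Subgroups were also compared between ages. The names rest on clusters made in each library alone, since in joint clustering the FIP-like cluster of 1149 cells and the APC-like cluster of 1767 held 5-week cells only. Imprinted genes were higher and chemokines lower at the perinatal ages in FIP-like and APC-like cells, and at P7 in F3-like cells, which were not named at P3. Imprinted genes had medians of 2.07 in P3 over 5 weeks and 2.22 in P7 over 5 weeks in FIP-like cells, of 2.74 and 2.91 in APC-like cells, and of 1.10 in P7 over 5 weeks in F3-like cells. Chemokines had medians of -2.00 and -2.96 in FIP-like cells, -2.90 and -2.76 in APC-like cells, and -3.29 in F3-like cells. Early response genes of dissociation were lower in F3-like cells at P7 as well, with a median of -1.06 when thinned, 16 of 31 lower and 3 higher. In P3 over P7, chemokines had a median of 1.31 in FIP-like cells, with 13 higher and 1 lower among 21, and of -0.22 in APC-like cells. Ccl2 stood at 545 CPM at P3 and 89.0 at P7 in FIP-like cells, a log2 ratio of 2.61, and its P7 level lay below the 597.5 CPM of P7 free RNA. Cholesterol synthesis genes had a median of 1.06 in these cells. In APC-like cells Dlk1 stood at 3275 CPM at P3 and 5.00 at 5 weeks, and Ccl7 at 25 and 6841. Adipogenic genes of APC-like cells had a median of 0.48 in P3 over 5 weeks, which turned to -0.30 with TMM scaling, and of 0.53 in P3 over P7. Genes beyond 2-fold in P3 over 5 weeks were 736 higher and 722 lower in FIP-like cells and 1113 and 851 in APC-like cells. With TMM scaling these splits were 345 and 956, and 332 and 1250. In P7 over 5 weeks the splits were 561 and 620 in FIP-like, 835 and 686 in APC-like and 681 and 610 in F3-like cells, and with TMM scaling 248 and 829, 327 and 892, and 315 and 799.

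Mesothelial-like cells at the perinatal ages carried higher RNA of the imprinted gene Nnat, of the growth factor Mdk and of the simple epithelial keratins Krt7 and Krt19. Their identity genes Msln and Upk3b differed little between the ages. Prostaglandin synthase Ptgs2, complement C3 and Thbs1 were lower than at 5 weeks. Msln (ENSMUSG00000063011, chromosome 17, 25748613 to 25754378) stood at 889 CPM at P3, 610 at P7 and 764 at 5 weeks, and Upk3b at 1496 CPM at P3 and 1427 at 5 weeks. Nnat stood at 163 CPM at P3, 71.0 at P7 and 2.30 at 5 weeks, against 70.0 in P3 and 21.0 in P7 free RNA. Mdk stood at 551 CPM at P3, 568 at P7 and 68.1 at 5 weeks, against 491 in P3 and 351.5 in P7 free RNA. Dlk1, at 821.7 CPM at P3 and 572 at P7, and H19, at 90.7 and 70.0 CPM, lay below the free RNA of their libraries, so their higher levels than at 5 weeks were not read as mesothelial. Krt7 stood at 651 CPM at P3, 554 at P7 and 146.5 at 5 weeks, and Krt19 at 1308 and 547 at P3 and 5 weeks. The list of mesothelial keratins and membrane genes went both ways in P3 over 5 weeks, with a median of 0.39, 5 higher and 6 lower among 20. In P7 over 5 weeks its median of 0.03 turned to -0.03 with TMM scaling. Ptgs2 stood at 40.5 and 378.6 CPM at P3 and 5 weeks, and C3 at 1333 and 4974. Ccl2 stood at 160 and 610 CPM, below the free RNA of both libraries, which held 3561 CPM at 5 weeks. Its ratio was therefore not read as mesothelial, and the chemokine medians below include it. In P3 over 5 weeks medians were 1.79 for 16 imprinted genes, 1.80 for 46 G2M genes, -1.14 for 27 chemokines, -1.15 for 22 TGF-beta genes, -1.19 for 14 basement membrane genes and -0.90 for 16 MHC class I genes. In P7 over 5 weeks the medians were 1.38 for imprinted genes, 2.03 for G2M genes, -1.31 for chemokines and -0.90 for TGF-beta genes. Between P3 and P7, MHC class II genes had a median of 1.84, and Cd74, the class II invariant chain, stood at 299 and 73.9 CPM, although P3 free RNA held 260. Chemokines had a median of 0.61 there, with Ccl7 at 110.0 and 27.6 CPM, below the 341 and 392 CPM of P3 and P7 free RNA, so its ratio was not read as mesothelial. Beyond 2-fold, 406 genes were higher and 714 lower in P3 over 5 weeks, 442 and 615 in P7 over 5 weeks, and 50 and 25 in P3 over P7. With TMM scaling the last split was 64 and 17.

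Macrophage- and monocyte-like cells at the perinatal ages carried higher RNA of Timd4, Pf4 and C1qa, and at 5 weeks far more of MHC class II, which presents antigen to helper T cells. Timd4 marks self-renewing resident macrophages, Pf4 and Lyve1 accompany them, and Spp1 and Trem2 mark lipid-handling macrophages. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419) stood at 211 CPM at P3 and 5205 at 5 weeks, and Cd74 at 970 CPM at P3, 683 at P7 and 14630 at 5 weeks. Over 10 MHC class II genes the median was -3.42 in P3 over 5 weeks and -4.25 in P7 over 5 weeks, each with 8 lower and 0 higher. The dendritic markers include H2-Aa, H2-Ab1 and Cd74, so class II genes took part in deciding which clusters were counted in this class. The class II ratios are therefore not independent of that choice. At P7 a myeloid cluster of 240 cells was counted as dendritic, with a dendritic score of 3.54 and a macrophage score of 3.49. All P7 values of this class leave out these cells. A P3 cluster of 178 cells led by Il1b, with H2-Aa and Ccr2 among its leading genes, was counted. Timd4 stood at 417 CPM at P3, 265 at P7 and 41.1 at 5 weeks, Pf4 at 4954 at P3 and 1072 at 5 weeks, and C1qa at 4217 and 1369. At 5 weeks a myeloid-scoring cluster of 41 cells with Timd4 among its leading genes stayed unnamed and was left out. A P7 cluster of 139 cells with like leading genes was counted, so the 5-week Timd4 level lacks such cells. Retnla, of alternatively activated macrophages, stood at 43.0 CPM at P3, 417 at P7 and 21380 at 5 weeks, and the monocyte receptor Ccr2 at 154 and 586. Over 15 resident macrophage genes the median was 0.27 in P3 over 5 weeks, which turned to -0.17 when thinned, 1.49 in P7 over 5 weeks and -0.85 in P3 over P7. Inflammatory genes had a median of 1.62 over 17 members in P3 over P7, with 12 higher and 0 lower. That difference carries the limit of cluster make-up given above, and its cause was not tested. Il1a stood at 148 CPM at P3 and 18.4 at P7, Spp1 at 191 and 16.7, and Mrc1 at 409 and 887. Lipid-associated macrophage genes had medians of 0.66 in P3 over 5 weeks and 0.51 in P7 over 5 weeks, with Trem2 at 309.8 CPM at P3 and 48.8 at 5 weeks. G2M genes had medians of 2.07 and 1.57 against 5 weeks. Beyond 2-fold, 624 genes were higher and 713 lower in P3 over 5 weeks, 677 and 608 in P7 over 5 weeks, and 91 and 72 in P3 over P7. With TMM scaling the splits were 421 and 833, 267 and 873, and 143 and 46.

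Endothelial-like cells could be compared between P7 (124 cells) and 5 weeks (991 cells), since P3 had 28. At P7 they carried less RNA of Scd1 and Cd36, of class I antigen presentation and of interferon response, and more of the apelin receptor Aplnr, which marks venous and sprouting vessels. Scd1, which desaturates fatty acids, stood at 35.5 CPM at P7 and 1413 at 5 weeks, a log2 ratio of -5.32. Cd36, the fatty acid transporter, stood at 1901 and 5094 CPM and the water channel Aqp1 at 477 and 1841, while Fabp4 stood at 45640 and 45770. Adipocyte was the second-scoring class of the 5-week endothelial clusters, with scores of 3.79 and 3.48, and the adipocyte genes Cfd, at 87.4 and 1113 CPM, and Plin4, at 1.18 and 30.3, moved in the same direction, so the lipid genes cannot be read as endothelial alone. Aplnr stood at 470 and 51.4 CPM, and Cdkn1a, which halts the cell cycle, at 29.5 and 1289. The cell junction gene Cldn5 stood at 1163 and 4131 CPM, Cdh5 had a log2 ratio of -1.02 and Pecam1 of -0.76. Over 16 endothelial lipid handling genes the median was -0.58, with 4 lower, 1 higher and 11 within 2-fold, and with TMM scaling -0.96, with 8 lower and 1 higher. Medians were -1.40 for 36 adipogenic and lipid storage genes, -1.47 for 17 MHC class I genes, -1.59 for 26 interferon response genes and -0.94 for 21 tip and sprouting genes. Early response genes of dissociation were lower as well, with a median of -1.18 and 17 of 31 lower. G2M genes had a median of 0.95, which was 0.51 with TMM scaling and 1.91 when thinned. Imprinted genes had a median of 2.75 and matrix genes of 2.11, but Dlk1 at 447 CPM lay below the 925 CPM of P7 free RNA, so these lists were not read as endothelial. Pericyte genes were also higher in the P7 class, with Acta2 at 190.2 and 0.925 CPM and Tagln at 184.3 and 12.2, while 5-week clusters of 121 and 624 cells that mixed endothelial and pericyte genes stayed unnamed. Beyond 2-fold 700 genes were higher and 876 lower, and with TMM scaling 267 and 1267.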

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

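All tests below were chosen only after the result they bear on was seen, except the test of doublet scores. Several gene lists differed between FIP-like and APC-like progenitors in opposite directions at different ages, and these differences between ages were not tested. The median log2 ratio of FIP-like over APC-like cells for chemokines and inflammatory mediators was 0.85 at P3, -0.22 at P7 and -0.60 at 5 weeks. For the insulin-like growth factor axis it was -0.55 at P3, -0.29 at P7 and 0.47 at 5 weeks. Glucocorticoid-responsive genes had medians of 0.35 at P3 and -0.54 at 5 weeks. For interferon response genes the medians were 0.29, -0.47 and -0.88 at P3, P7 and 5 weeks. Early response genes had medians of 0.51, -0.22 and -0.79. Wnt pathway genes had medians of 0.59 at P3 and -0.40 at 5 weeks. Some P3 medians turned under other settings, those of Wnt and glucocorticoid-responsive genes to -0.09 and -0.07 when thinned and that of interferon response to -0.09 at resolution 1.0. The P7 median of chemokines turned to 0.07 at resolution 1.0. Cholesterol synthesis genes had medians of 0.33 at P3, 0.11 at P7 and -0.58 at 5 weeks.

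Some genes had a high signal under Ensembl IDs that only some of the gene lists hold, and they were outside every comparison. Cebpd, an early regulator of fat cell formation, stood at 705.7 CPM in P3 and 798.4 CPM in P7 progenitor-like cells. Pnp stood at 274.4 CPM at P3 and 224.6 CPM at P7, and the ID that bears this symbol in the 5-week list is named Gm49342 in the others. Ifi30, a lysosomal gene of antigen processing, stood at 133.0 CPM in 5-week progenitor-like cells. IDs outside the shared set held 0.191% of progenitor UMIs at P3, 0.203% at P7 and 0.0889% at 5 weeks.

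A set of genes stood at least 8-fold apart between the perinatal and 5-week libraries in one direction, in progenitor-, mesothelial- and myeloid-like cells and in free RNA. The ratios varied between classes, as for Nr4a3, named after its values were seen, at -6.31 in progenitors and -3.54 in mesothelial-like cells in P3 over 5 weeks. Of the 10 that were higher at 5 weeks, 40% were overlapped on the same strand by a gene model that only the P3 and P7 list holds [12.2 to 73.8], against 0.749% of 9215 other genes. This is consistent with counts that moved to other gene models in the newer list, and the overlapped genes, named after their values were seen, were Sept2, Fdx1l, Hgs and Tonsl. The 14 that were higher at P3 and P7 include ribosomal protein genes, named after their values were seen. In progenitors Rpl15 stood at 2131, 2045 and 102.7 CPM at P3, P7 and 5 weeks, and Rpl23a at 888.3, 779 and 26.52. Of the 14, 0.0% were overlapped by a model of the 5-week list alone [0.0 to 23.2]. That test sees only overlap on the same strand and had coordinates for 50% of the 5-week IDs. A change of annotation and other causes therefore cannot be told apart for the 14. A biological difference at 5 weeks in these genes was not tested.

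The low level of chemokine and inflammatory genes in perinatal progenitors, with list medians of -2.78 in P3 and -3.08 in P7 over 5 weeks, was weighed against technical causes. Free RNA as the source is argued against, since 22 of 22 members higher at 5 weeks lay above the limit of 0.102 that Mki67 and Top2a set for cell over free RNA level, with a median of 1.81. Thinning cannot decide on cell depth, since it draws UMIs at random within each cell and leaves the expected CPM of a cell unchanged. For P3 over 5 weeks the thinned median was -2.94, outside the random range of -0.33 to 0.74. That value shows only that the P3 difference did not rest on deeper cells weighing more in the class sum. A stronger response to dissociation of the 5-week tissue may contribute, since early response genes had a median of -1.27 in P7 over 5 weeks, below the random range, although Jun, named after its values were seen, stood at 4280 CPM at P7 and 1110 at 5 weeks. For P3 over 5 weeks the early response median of -0.12 lay within the random range of -0.39 to 0.61 while 12 of 31 members were lower, so that response and age cannot be told apart there, and age stays open as untested for both pairs.

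At 5 weeks 1078 cells scored as endothelial together with another class. Their median of 10530 UMIs was 2.76 times the 3820 UMIs of the named endothelial-like cells. Their median Scrublet score of 0.0372 was 2.27 times the 0.0164 of the named cells. Multiplets that hold an endothelial cell are therefore a candidate explanation, and large cells with mixed expression stay open. A biological difference with age was not tested.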

How the results depend on the processing

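The mitochondrial limit of 20%, the inclusion of a P3 cluster with a pericyte marker, the annotation and ratio filters, and scaling, depth and minimum alternatives in other classes and subgroups were chosen after seeing the data. A list median counts as reversed only where its sign turned and its first value lay outside the middle 95% of random lists, so sign turns of medians inside that range are counted as moved or, within a log2 of 0.25, as the same. Of the list medians, 1830 values stayed the same, 698 moved and 11 reversed. Of the log2 ratios of named genes, 2278 stayed the same, 844 moved and 6 reversed. TMM scaling moved 288 list medians and no minimum 172. The cause of the changes was not tested, except where construction shows it.

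Without cells that carry cycling UMIs, cell cycle genes reversed by construction, with the G2M median in P3 over P7 at -0.05 and log2 ratios of -0.21 for Cdk1 and Mki67 in P7 over 5 weeks and of -0.22 for Kif2c and -0.10 for Ndc80 in P3 over P7. The marker gate keeps only cells without Pecam1 UMIs, so Pecam1 turned to 0.60 in P3 over 5 weeks by construction. Both of its counts were 0, and the value reflects only the floor of 3 counts and the class sums. S100a8 turned to -1.97 with that gate in P3 over P7. In FIP-like cells the keratin list in P3 over 5 weeks turned to -0.73 with TMM and -0.22 thinned, and complement in P3 over P7 to 0.01 with no minimum. In APC-like cells inflammatory macrophage genes in P3 over 5 weeks turned to 0.07 with no minimum, and early response in P3 over P7 to 0.04 at resolution 1.0. In F3-like cells TGF-beta genes in P7 over 5 weeks turned to 0.08 when thinned. For FIP-like over APC-like cells at P3, glucocorticoid-responsive and Wnt genes turned to -0.07 and -0.09 when thinned and interferon response to -0.09 at resolution 1.0, and at P7 chemokines turned to 0.07 at resolution 1.0.

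The cycling shares of progenitors at P3, P7 and 5 weeks were 28.1%, 8.13% and 1.49% without thinning and 75.6%, 61.2% and 38.8% with 2 UMIs over the G2M list, which counts more genes. Thinning to 1000 UMIs gave 10.1% at P3 and 3.81% at P7. In progenitors, TMM scaling gave 364 higher genes in P3 over 5 weeks and 256 in P7 over 5 weeks. A minimum of 10 CPM tests more genes and gave 2421 higher and 1461 lower, 2200 and 1188, and 293 and 140 for P3 over 5 weeks, P7 over 5 weeks and P3 over P7. A minimum of 200 CPM gave 193 and 265, 130 and 235, and 23 and 16. For FIP-like over APC-like cells, joint clustering gave 189 higher at 5 weeks, resolution 1.0 gave 253 and 169 at P7, and thinning gave 301 lower at P3. Joint sub-clustering named no such pair at P3 or P7, so it gave no value there.

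Class shares moved in 38 of the values and stayed in 46, and the 12 values of cells kept stayed within 1.5 times the main ones. With Scrublet calls kept in, progenitor-like cells were 46.2% at P7 and 36.6% at 5 weeks, myeloid-like 17.5% and 15.6%, and at 5 weeks endothelial-like 12.1% and mesothelial-like 0.0%, since that cluster lost its name. With 200 genes and 500 UMIs, progenitor-like cells were 24.6% at P3 and 46.6% at P7, mesothelial-like 26.6% and 16.4%, myeloid-like 11.8% and 14.9%, and endothelial-like 1.39% at P7. With cells called by markers, where a single UMI of a low marker can decide, P3, P7 and 5 weeks gave 10.0%, 14.1% and 9.65% progenitor-like, 13.7%, 8.77% and 3.93% mesothelial-like, 8.70%, 10.5% and 19.4% myeloid-like, and 0.0879%, 0.358% and 14.2% endothelial-like cells. With a mitochondrial limit of 20%, progenitor-like cells were 39.9% at P3 and 33.4% at 5 weeks, mesothelial-like 31.7%, 17.2% and 5.21%, myeloid-like 28.6% at 5 weeks, and endothelial-like 1.47% at P7 and 14.7% at 5 weeks. Resolution 0.5 gave 0.0% endothelial-like at P3, 47.7% progenitor-like at P7 and 19.3% myeloid-like at 5 weeks, and resolution 2.0 gave 11.4% and 20.6% myeloid-like at P3 and 5 weeks. The number of cells limits what can be compared, with 28 endothelial-like cells at P3.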

Other observations

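Some progenitor sub-clusters, which held most of the P3 progenitor-like cells, got no subgroup name, and their leading genes give a partial picture. At P3 a group of 304 cells was led by Top2a, Prc1 and Cenpf, genes of mitosis, and a P7 group of 223 cells by Cenpf, Ube2c and Top2a. A P3 group of 546 cells was led by Rspo3, a Wnt enhancer, and Sult1e1, and a P7 group of 731 cells by Cnmd, Igfbp3 and Rspo3. At P3 502 cells were led by Il33, an alarm cytokine of stromal cells, and 109 by Igfbp2. At 5 weeks 656 cells were led by Peg3 and Mest, which are imprinted genes. Small groups led by genes of other cell types stayed in the progenitor sums, with 23 cells led by Ccl5, Il5 and Gzma and 31 led by Gpihbp1, Flt1 and Cldn5 at 5 weeks, and 17 led by Rgs5, Tinagl1 and Myh11 at P7. These leading genes were read after the groups had been formed and were compared with no other age.

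Free RNA differed between the libraries in amount and kind. Barcodes of at most 100 UMIs held 1.74% of UMIs at P3, 2.11% at P7 and 4.95% at 5 weeks. Fabp4 stood in that free RNA at 239 CPM at P3, 2526 at P7 and 12570 at 5 weeks.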
